A study of Mus musculus with 11 samples.

How the data were processed

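RNA of 11 mouse lymphomas was measured on one-colour arrays, 4 plasma cell lymphomas (PCL), 3 mantle cell lymphomas (MCL) and 4 Burkitt lymphomas (BL), grouped by the tumour origin that the labels give. Total RNA, 0.2 micrograms per sample, was labelled with Cy3 by a low-input amplification kit, per the labels' protocols, and the RNA integrity numbers in the labels ranged from 8 to 10. The design text numbers its mantle cell samples up to 4 and also counts 3, and 3 were analysed here. The labels do not say that every tumour came from a different mouse, so the p-values measure only the spread between these samples, which may be technical. Replicate numbers are the array positions on a slide, and each type occupied 1 slide, so a term for slide could not be fitted.

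The scanner files of the authors hold spot brightness, extracted with Agilent Feature Extraction 10.7.3.1, per the file headers. In these deposited files the processed signal is an intensity on a linear scale. Spatial and multiplicative detrending within the array were on and a separate background adjustment was off, per the file headers, and nothing was normalized between arrays. On every array the background subtracted from a spot's mean was the fitted spatial surface (100% of spots), with a median of 39.0 to 64.0 intensity units. Between 21.5% and 29.2% of the spots of an array hold a substitute value that the software set for spots not above background, so ratios of dim probes depend on this treatment. The mean signal and the median local background, raw intensity values as deposited, served an alternative background correction. The series also has a value table of the authors, in log2 units found from the data. Its ranks equal those of the median spot signal of the same array (Spearman correlation of 1). The columns share nearly one distribution, with medians from 7.25 to 7.26, so it appears normalized between arrays and not centred by gene. The equal ranks point to no background subtraction by spot, but a constant subtracted from a whole array would also keep them. How the authors made the deposited log2 table is not given in the sources used here. It holds 43209 values per array, 189 of them of control spots, and was used as an alternative.

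Of each array, 43020 non-control spots of 39429 probes were read. Spots marked as non-uniform or population outliers were left out, and remaining spots of a probe were averaged. The 46 probes without a spot left on some array were left out of all arrays. Of the spots 0 were saturated. The log2 of the processed signal minus the array's 75th percentile was used, and probes well above background on at least 3 arrays were kept, which left 25296 probes. Probe coordinates are those of mouse build mm9, per the file headers, and a mouse annotation of assembly GRCm38.p6 was used for gene names only. Accessions named 26581 probes, current symbols 2597 and older symbols 492, and 9759 kept the name in the files. The probe with the highest mean over all arrays stood for a gene, which left 20181 genes. Of these, 13814 counted as named genes, and the other 6367 were unnamed transcripts, pseudogenes or variable segments of antigen receptors. The 75th percentile of the arrays lay between 1072 and 1637 intensity units, 55.5% to 62.8% of the spots were well above background, and the coefficient of variation of replicate probes was 3.32% to 4.25%.

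Differences were tested with limma 3.58.1 in R 4.3.3, in a fit of all 11 arrays with a mean per type, so that the 8 residual degrees of freedom and a prior of 2.01 are shared by the comparisons. A moderated F test asked for any difference among the 3 types, and contrasts compared PCL with MCL, PCL with BL and MCL with BL. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes were called. Every adjusted p given for a gene comes from this fit, and differences are on the log2 scale, the first-named type minus the second. The median standard error of a difference was 0.31 log2 units between PCL and MCL. Where a probe was not well above background on any array of a type, the ratio is given as a lower bound. It is the mean of the brighter type against the mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. The bound concerns that probe after this background subtraction, and other background treatments can give less.

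The grouping of tumours was tested by the share of squared distances that lies between types, against all 11550 assignments of the arrays. Lists of genes were tested with limma's camera at its preset correlation of 0.01, adjusted over the 22 lists of a comparison. Camera compares a list's genes with all other genes, so its direction is relative to those and not to 0. Alternatives were camera with an estimated correlation and fry, which tests whether a list's genes move one way. The lists were the plasma cell programme, mature B cell identity, germinal centre, precursor B cell, genes associated with mantle cell and with Burkitt lymphoma, MHC class II presentation, immunoglobulin constant regions, Myc targets, p53 targets, cell cycle, secretory pathway and unfolded protein response, NF-kB targets, interferon response, Bcl2 family, immediate early and heat shock genes, and markers of T cells, cytotoxic cells, macrophages and monocytes, granulocytes, stroma and endothelium, and erythroid cells. The groups, tests, lists, the rule for naming genes and all alternatives but 3 of the 29 were chosen before the data were examined.

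By that rule the text names, per comparison, the 8 genes with the largest rise and the 8 with the largest fall among called genes whose arrays did not overlap and that were well above background on every array of the higher type, leaving out unnamed transcripts, pseudogenes and variable segments. It further names up to 4 called members of each list, or, of a list with none called, members with the smallest unadjusted p as values, and 9 genes in every comparison. Alternatives were quantile normalization, normexp background correction with an offset of 50, the authors' value table, other filters on dim probes, the mean of a gene's probes, a trended and robust prior, array weights, the RNA integrity number, the array position as a block, a fit of only the groups compared, a minimum of 2-fold, other list tests, another distance, and leaving out each array.

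The steps were tested on simulated data with 200 of 20181 genes changed. Between PCL and MCL, 25.4%, 59.7% and 84.8% of genes changed by 1, 2 and 4 log2 units were recovered. There 14 unchanged genes were called, 11.0% of the calls. Between PCL and BL the shares recovered were 32.8%, 71.6% and 92.4%, with 8 unchanged genes called (5.76% of the calls). Between MCL and BL they were 20.9%, 61.2% and 86.4%, with 8 (6.67%). With no gene changed, limma called 0 genes. The simulated noise was independent between genes, with the same spread on every array and no slide effect. These values therefore do not measure false calls in the real data. Tables were read with the R package data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9.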

Results

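Gene expression was measured in 11 lymph node lymphomas from mice of the Black 6 strain that carried c-myc-3'RR, a c-myc transgene controlled by the 3' regulatory region of the immunoglobulin heavy chain locus, and were heterozygous for p53. The tumours were 4 plasma cell lymphomas (PCL), 3 mantle cell lymphomas (MCL) and 4 Burkitt lymphomas (BL), each hybridised to its own one-colour array and named here by type and replicate number, such as PCL1. Between 55.5% and 62.8% of the 43020 non-control spots of an array were well above background, and the number of arrays limits the precision of every comparison. Each type lay on a slide of its own, so differences between types and differences between slides cannot be told apart.

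The series set the 3 lymphoma types of this mouse model against each other, and the first question was whether tumours of a type resembled each other more than tumours of other types. Lymphoma type accounted for 35.3% of the total squared distance between tumours over 20181 genes (exact permutation test over 11550 assignments, large values only, p = 0.00416). Across genes, which are not independent replicates, the mean correlation of log2 signals within a type was 0.961 in PCL, 0.943 in MCL and 0.956 in BL. Between types it was 0.929 for PCL with MCL, 0.945 for PCL with BL and 0.945 for MCL with BL. MCL tumours thus correlated no better among themselves than with BL tumours. PCL1 stood apart from its group: it correlated at a mean of 0.945 with PCL2 to PCL4, which correlated at 0.977 among themselves, and at 0.952 with the BL tumours. The macrophage markers separated the same tumours, with a median of -0.95 in PCL1 and of 2.58, 1.29 and 1.57 in PCL2 to PCL4 (log2, each gene centred on its mean over the 11 tumours). In a moderated F test, 1701 genes differed among the types, 8.43% of those tested.

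**Figure D1:**
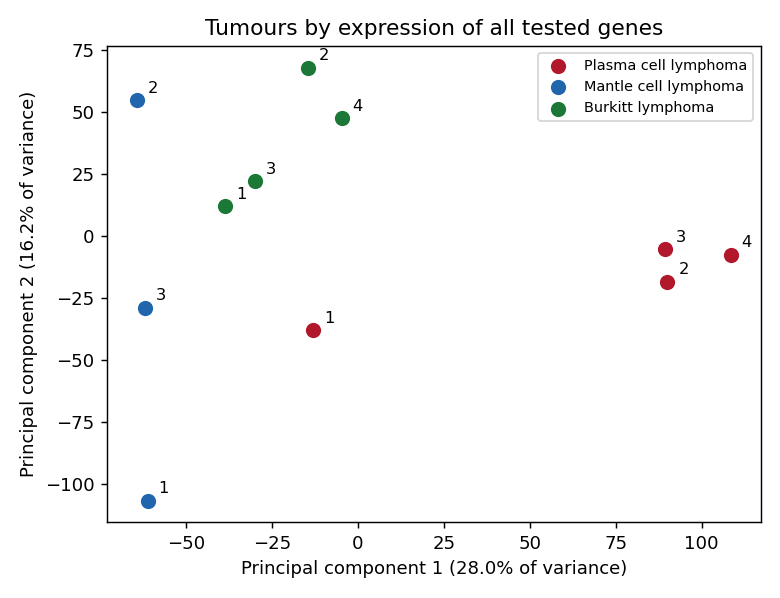
Principal components 1 and 2 of the log2 signals of 20181 genes, with 28.0% and 16.2% of the variance on the axes and a point per tumour, numbered by replicate and coloured by type. PCL2 to PCL4 lie at one end of component 1, and PCL1 lies nearer the BL and MCL tumours.

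PCL tumours had higher signals than MCL tumours for Rag1 and Prss12, and lower signals for the B cell genes Spib and Fcmr. The mature B cell identity genes did not fall as a set, as 11 of 20 were higher in PCL. Rag1, a subunit of the recombinase that assembles antigen receptor genes, reached a log2 signal of 1.84 ± 2.61 (SD, n = 4) relative to each array's 75th percentile. It was not well above background in any of the 3 MCL tumours, so it was at least 234-fold higher in PCL (limma, log2 difference 9.79 ± 1.62, SE, adjusted p = 0.0111). Prss12, a secreted serine protease, was at least 384-fold higher in PCL (adjusted p = 0.000188), at 2.56 ± 0.90 (SD, n = 4) against -7.18 ± 0.68 (SD, n = 3). Such bounds hold for the background-subtracted signal only: with normexp correction and with the authors' values, all 18 differences with a bound that were refitted were smaller than it, such as 6.35 and 6.64 for Rag1 and 6.53 and 6.65 for Prss12. Another Rag1 probe differed by 6.33. Transcripts of Spib, a B cell transcription factor, fell by 2.06 on the log2 scale in PCL relative to MCL (adjusted p = 0.00813), and those of Fcmr, the Fc receptor for IgM, fell by 3.06 (adjusted p = 0.0197). Ccnd2, the gene of cyclin D2, had a log2 signal of -0.52 ± 1.24 (SD, n = 4) in PCL and of 2.58 ± 0.53 (SD, n = 3) in MCL (adjusted p = 0.0191). Ccnd3, the gene of cyclin D3, was higher in PCL by 1.61 (adjusted p = 0.0395).

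Of the 20181 genes, 1401 differed between PCL and MCL, 429 of them higher and 972 lower in PCL. Of the 1401, 935 differed by at least 2-fold. In 1385 of the called genes the arrays of the 2 types did not overlap, which held for 22.9% of all genes where chance gives 5.71%. The other large rises in PCL were those of Rd3l (9.47), Trim63, a ubiquitin ligase known from muscle (8.23, at least 71.1-fold), Tmem255a (7.92), and Arap3, a GTPase-activating protein (7.74). Large rises were also those of Uchl1, a deubiquitinating enzyme (7.52, at least 50.7-fold), and Hey1, a transcriptional repressor induced by Notch (7.43, at least 47.2-fold). Other probes of the same genes gave smaller rises, 2.94 for Tmem255a, 6.43 for Trim63 and 2.86 for Arap3. PCL1 lay below the other PCL tumours for several of these genes, as for Trim63, at -5.41 against 1.83 in the nearest. The largest falls were those of Iglon5 (-6.28), Havcr1, which encodes the surface receptor TIM-1 (-5.33), Serpine2, a protease inhibitor (-3.90), and Arntl2 (-3.87). Other probes gave -3.47 for Havcr1 and -5.27 and -4.36 for Arntl2. Large falls were also those of Tcstv3 (-3.84), the interleukin receptor gene Il17rb (-3.67), Adm, which encodes adrenomedullin (-3.64), and Sema5a (-3.63). The calls of Rag1, Prss12, Rd3l, Arap3, Uchl1 and Hey1 held in all 21 other settings in which they were tested and that of Spib in all 22. The other genes named for this comparison lost theirs in at least 1. Iglon5 (limma, adjusted p = 0.0495) lost its call in 15 of 21 settings and Havcr1 (adjusted p = 0.0497) in 13 of 21. Of the list members named below, Cd14 lost its call in 19 of 22, Trp53inp1 in 15 of 22 and Blk in 14 of 22.

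Among the members of 22 gene lists, 314 distinct genes were measured, and 22 of them differed between PCL and MCL, 8 higher and 14 lower in PCL. For comparison, 843 of all 13814 named genes were called, 333 higher and 510 lower in PCL. Of 20 mature B cell identity genes, 3 were called, all lower in PCL, namely Spib, Fcmr and the kinase gene Blk (-1.26), while 11 were higher. Of 16 NF-kB targets, 3 fell: Rel (-2.78), Bcl3 (-1.42) and the survival gene Bcl2a1d (-3.14). Of 24 cell cycle genes, 2 fell: the mitotic kinase gene Aurkb (-2.15) and Ccne1, which encodes cyclin E1 (-1.30). Of 12 MHC class II presentation genes, only Ciita, the transcriptional activator of the class II genes, was called (-2.39, adjusted p = 0.015). In the plasma cell programme, 0 of 16 members passed, and Mzb1, a chaperone of antibody secretion, had a difference of 0.88 (adjusted p = 0.0851). Single members were also called for the Bcl2 family (Bid, -0.95), T cells (Cd4, -0.78), cytotoxic cells (Prf1, -0.82) and granulocytes (Elane, -1.02). The medians of these 4 lists went the other way, at 0.15, 0.22, 0.40 and 1.90, and 12 of 13 granulocyte markers were higher in PCL. Single members were higher for Myc targets (Eif4a1, 0.76), p53 targets (Trp53inp1, 1.17), immediate early genes (Atf3, 3.35) and immunoglobulin regions (Igh-VJ558, 5.19, and 5.11, 4.70, 3.73 and 0.07 by other probes). Ccnd2, Bid and Cd4 lie on chromosome 6 and Spib, Bcl3, Ccne1, Iglon5 and Adm on chromosome 7. Among genes with signals above the median of all genes, those of chromosomes 6 and 7 had a median difference of -0.54 and of -0.37 between PCL and the mean of the other types (exact permutation test, adjusted p = 0.0606 for both). PCL1 did not share it, at 0.04 on both.

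The macrophage and monocyte markers passed the list test, with a median difference of 2.16 between PCL and MCL and 16 of 17 genes higher in PCL (camera, adjusted p = 3.81e-06; adjusted p = 0.829 with an estimated correlation). The list's median in PCL1, -0.95, was below that of MCL1, 0.34, so PCL1 did not share the rise over all MCL tumours. Of these genes, 2 were called, the scavenger receptor gene Msr1 (2.06, adjusted p = 0.0314) and Cd14 (2.00). The other 21 lists did not pass (adjusted p from 0.084 to 0.869), and for mature B cell identity the median was 0.08, the mean -0.28 and the test downward. Leaving out PCL1 raised the count of differing genes to 2463. The count was 333 without PCL2, 551 without PCL3, 338 without PCL4, 693 without MCL1, 476 without MCL2 and 700 without MCL3. With another background correction (normexp) it was 197, of which 91 were higher in PCL. It was 4424 with array quality weights.

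**Figure D2:**
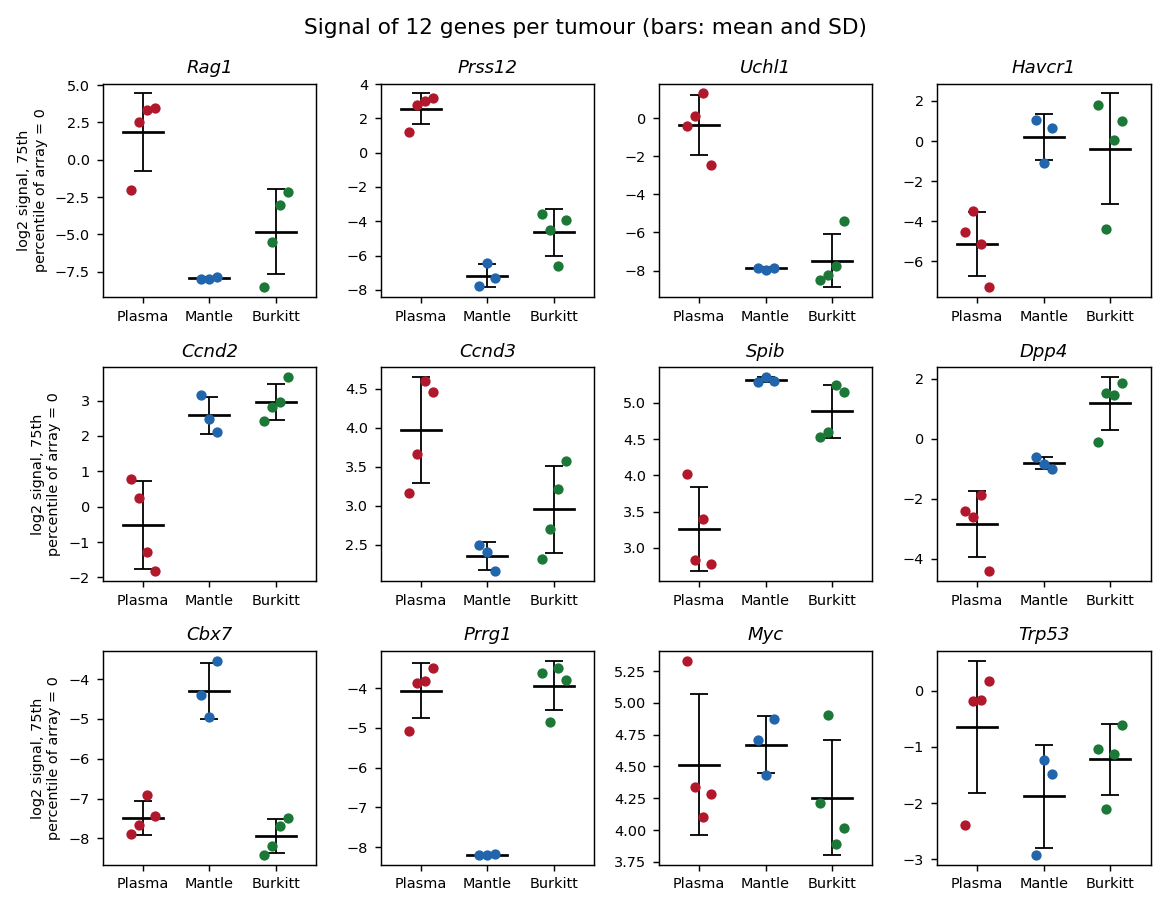
Log2 signal of 12 genes in each of the 11 tumours, relative to the 75th percentile of the array, with a point per tumour and bars for the mean and SD of each type. Rag1, Prss12 and Uchl1 are highest in PCL, Ccnd2 and Spib are lowest there, Cbx7 is highest in MCL, Prrg1 is lowest in MCL, and Myc lies between 3.89 and 5.33 in all tumours.

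Prss12, Uchl1, Arap3 and Hey1 rose in PCL against BL as they did against MCL, in a comparison with the same PCL tumours. Prss12 rose by 7.21 ± 0.68 (SE; limma, adjusted p = 0.00769), Uchl1 was at least 50.5-fold higher (adjusted p = 0.0117), Arap3 at least 103-fold by its brightest probe (adjusted p = 0.0201), and Hey1 had a difference of 6.79 (adjusted p = 0.0242). Another Arap3 probe differed by 3.39, and the brightest by 4.46 with normexp correction and by 4.92 with the authors' values. Slpi, the gene of a secreted leukocyte protease inhibitor, reached a log2 signal of 5.76 ± 0.35 (SD, n = 4) in PCL against -0.06 ± 1.19 (SD, n = 4) in BL (adjusted p = 0.0268). Dpp4, which encodes the surface peptidase CD26, was lower in PCL, at -2.83 ± 1.10 against 1.18 ± 0.87 (SD, n = 4 each; adjusted p = 0.0199). Ccnd2 fell by 3.49 (adjusted p = 0.0322). Of the Bcl2 family, the pro-apoptotic gene Bid fell by 1.65 (adjusted p = 0.0105).

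Between PCL and BL, 133 genes differed, 92 of them higher and 41 lower in PCL. The arrays of both types did not overlap in any of the 133. The remaining large rises were those of Tdrd9 (7.54, at least 76.6-fold), for which PCL1 lay at -3.82 and the nearest PCL tumour at 1.46, the actin-bundling gene Pls1 (6.23) and Smoc1 (5.73, at least 29.1-fold). Those lower in PCL were Daam2 (-3.73, at least 3.09-fold higher in BL), Btnl1 (-3.16, at least 3.59-fold higher in BL, but -1.64 by another probe), Apba1 (-2.58), Itpka (-2.55), Il4i1, an amino acid oxidase gene (-2.41), and Syne3 (-2.37). Of the genes named here, Prss12 kept its call in all 21 other settings in which it was tested, and the others lost theirs in at least 1. Itpka and Syne3 each lost theirs in 15 of 22.

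Of the 314 list members, 3 differed between PCL and BL, all lower in PCL: Ccnd2 and Bid, of chromosome 6, and Spib, of chromosome 7 (-1.63, adjusted p = 0.0447). For comparison, 111 of all 13814 named genes were called, 73 higher and 38 lower in PCL. By the camera test, 6 lists passed, although none did with an estimated correlation. The macrophage markers were higher in PCL in 17 of 17 genes, with a median of 1.55 (adjusted p = 0.000613, and adjusted p = 0.638 with an estimated correlation). The list's median was above those of the BL tumours in PCL2 to PCL4 only, and in PCL1, at -0.95, it was below all of them (-0.61 to 0.01). Examples were Msr1 (2.27, adjusted p = 0.0528) and the iron exporter gene Slc40a1 (2.47, adjusted p = 0.188). The plasma cell programme was higher in 12 of 16 genes, with a median of 0.48 (adjusted p = 0.0364, and adjusted p = 0.638 with an estimated correlation). Its list median was -0.21 in PCL1, below BL3 (-0.03) and BL4 (-0.13). The plasma cell programme held Sdc1, the gene of the plasma cell antigen CD138 (3.04, adjusted p = 0.0728), and Jchain (4.38, adjusted p = 0.106). Cell cycle genes were lower in PCL in 20 of 24 (median -0.27, adjusted p = 0.000678, and adjusted p = 0.638 with an estimated correlation). The list median of PCL3, 0.13, was above those of BL3 (0.07) and BL4 (0.06). Examples were Foxm1 (-2.16, adjusted p = 0.058) and Ccne1 (-1.29, adjusted p = 0.0621). NF-kB targets were lower in 11 of 16 (median -0.48, adjusted p = 0.00297, and adjusted p = 0.638 with an estimated correlation). PCL1, at -0.01, was above BL4 (-0.05). Members lower in PCL were Bcl3 (-1.05, adjusted p = 0.0867) and Relb (-0.70, adjusted p = 0.113). Mature B cell identity genes were lower in 13 of 20 (median -0.50, adjusted p = 0.0107, and adjusted p = 0.638 with an estimated correlation). PCL4, at 0.03, was above the lowest BL tumour, BL1. MHC class II genes were lower in 9 of 12 (median -0.40, adjusted p = 0.0364, and adjusted p = 0.647 with an estimated correlation). Here too PCL1 went the other way, with a list median of 0.39, above all BL tumours (-0.20 to 0.35). Examples were H2-DMb2 (-1.22, adjusted p = 0.276) and Ciita (-0.99, adjusted p = 0.234). Values of members of lists that did not pass were 1.11 for the chaperone gene Hsp90b1 (adjusted p = 0.0675), 3.99 for Atf3 (adjusted p = 0.0583), 1.92 for Jun (adjusted p = 0.0621) and 4.50 for Ighg, an immunoglobulin gamma chain probe (adjusted p = 0.122).

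The other 16 lists had adjusted p from 0.151 to 0.921 between PCL and BL. The median and mean differed in sign for the precursor B cell, Bcl2 family and immediate early lists, and the test differed from both for the T cell list. The count of 133 genes was 1074 without PCL1, 5 without PCL2, 37 without PCL3, 28 without PCL4, 36 without BL2, 45 without BL3 and 64 without BL4. The share higher in PCL, 69.2%, was 58.5% of 94 genes with quantile normalization, 50.6% of 166 in the authors' value table and 38.5% of 13 with normexp. Of the 133 genes, 95 had a mean signal below the median of all genes, and 84.2% of these were higher in PCL. The other 38 lay above it, and 31.6% of these were higher in PCL.

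**Figure D3:**
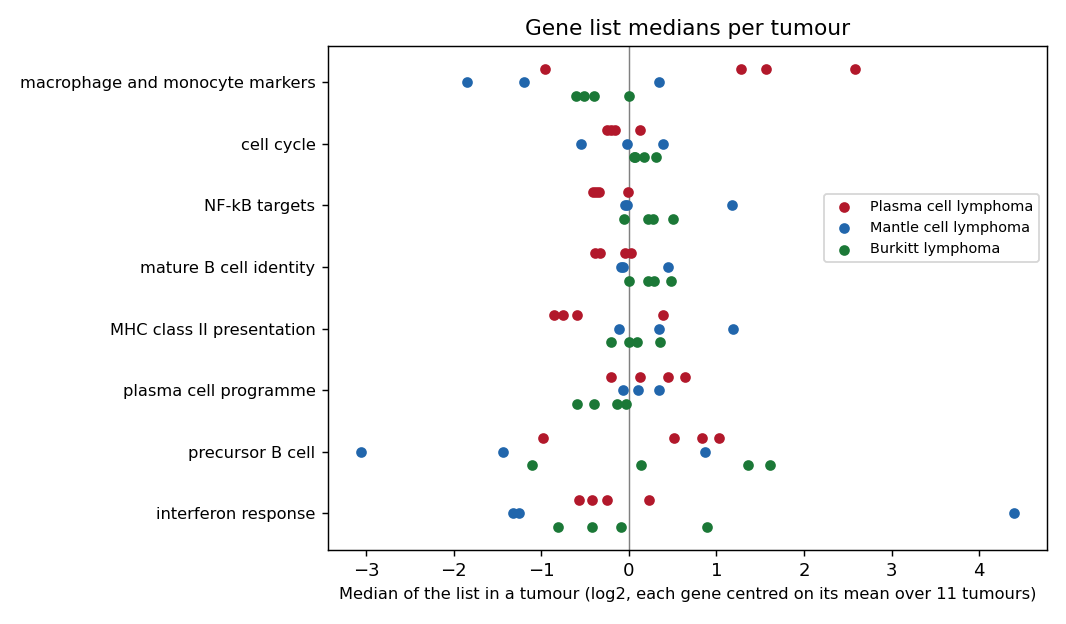
Median of 8 gene lists in each tumour (log2, each gene centred on its mean over the 11 tumours), with a point per tumour coloured by type. Macrophage markers lie between 1.29 and 2.58 in PCL2 to PCL4 and at -0.95 in PCL1, and the interferon response list lies at 4.40 in MCL1.

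MCL tumours differed from BL tumours in 1341 genes, of which 1301 were higher and 40 lower in MCL. S100a6, the gene of a calcium-binding protein, was at -0.24 ± 1.39 (SD, n = 3) in MCL and 3.54 ± 0.51 (SD, n = 4) in BL (limma, adjusted p = 0.00479). Maged1 fell by 2.26 ± 0.31 (SE, adjusted p = 0.00404). Prrg1 and Hmgcll1 were not well above background in any MCL tumour and were at least 4.25-fold and at least 4.16-fold higher in BL (adjusted p = 0.000796 and 0.00524). Cbx7, which encodes a Polycomb subunit, was not well above background in any BL tumour and was at least 3.57-fold higher in MCL (log2 difference 3.65 ± 0.37, SE, adjusted p = 0.000993). The size of these differences depended on the background treatment: that of Cbx7 was 1.27 with the authors' values and 0.51 with normexp correction, where it was not called. Hdc, the gene of histidine decarboxylase, was higher in MCL by 3.38 ± 0.74 (SE, adjusted p = 0.0239).

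The further rises in MCL were those of Clec2g (4.12, at least 5.55-fold), the GABA receptor subunit gene Gabra4 (3.96, at least 3.58-fold), the imprinted gene Snrpn (3.32, at least 2.73-fold), Uaca (3.08), Psg16 (3.00) and Enpp5 (2.93, at least 1.97-fold). With normexp correction the rises were 1.01 for Clec2g, 0.66 for Gabra4, 0.33 for Snrpn and 0.12 for Enpp5, none of them called, and with the authors' values they were 1.69, 1.5, 0.98 and 0.73. The further falls were those of Cracdl (-4.19), Ttll9 (-2.61), Armc3 (-2.19) and Gda (-2.06). Other probes of Cracdl and Hmgcll1 fell by 2.18 and 1.83. S100a6, Ttll9, Maged1 and Elane kept their calls in all 22 other settings in which they were tested. The other genes named for this comparison lost theirs in at least 1. Uaca lost its call in 17 of 21, Cracdl in 16 of 22 and Gda in 15 of 22. Over all 13814 named genes, 665 were called, 627 higher and 38 lower in MCL. Of the 314 list members 5 were called, all higher in MCL: Aurkb (2.14, adjusted p = 0.0213), Cd4 (0.96, adjusted p = 0.0142), the perforin gene Prf1 (1.16, adjusted p = 0.00723), the neutrophil elastase gene Elane (1.36, adjusted p = 0.00392) and the endothelial receptor gene Kdr (0.82, adjusted p = 0.0476). In all 5 of their lists the median of the members went the other way, at -0.18 for cell cycle genes, -0.03 for T cell, -0.44 for cytotoxic cell, -1.14 for granulocyte, and -0.46 for stroma and endothelium markers.

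The precursor B cell list was the only list past the threshold between MCL and BL, with 11 of 12 genes lower in MCL and a median of -2.58 (camera, adjusted p = 0.0267; adjusted p = 0.916 with an estimated correlation). Il7r, the receptor gene for interleukin 7, had a difference of -3.32 (adjusted p = 0.249). Dntt, the gene of terminal transferase, went the other way, with 0.73 (adjusted p = 0.0533). The list's median was -3.06 in MCL1, 0.87 in MCL2 and -1.44 in MCL3, so the MCL tumours did not share a level. The other 21 lists had adjusted p from 0.0984 to 0.848. For germinal centre genes, p53 targets and NF-kB targets the test pointed down while median and mean were above 0. The test's direction is relative to all other genes, so both can hold. For the mantle cell lymphoma associated list and Myc targets the sign also differed among median, mean and test.

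Of the 1341 genes, 1039 had a mean signal below the median of all genes, and 98.3% of these were higher in MCL. The other 302 lay above it, and 92.7% of these were higher in MCL. The median difference of all genes was 0.40 in decile 1, the dimmest, and -0.12 in decile 9. The 7 of 10 levels of spike-in control transcripts that lay above their floor had a median difference of 0.42 in the same direction. The arrays of both types did not overlap in 1339 of the called genes, and in 17.7% of all genes where chance gives 5.71%. The count was 687 without MCL1, 740 without MCL2 and 754 without BL2. It was 754 with quantile normalization, 680 with the authors' values and 65 with normexp.

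**Figure D4:**
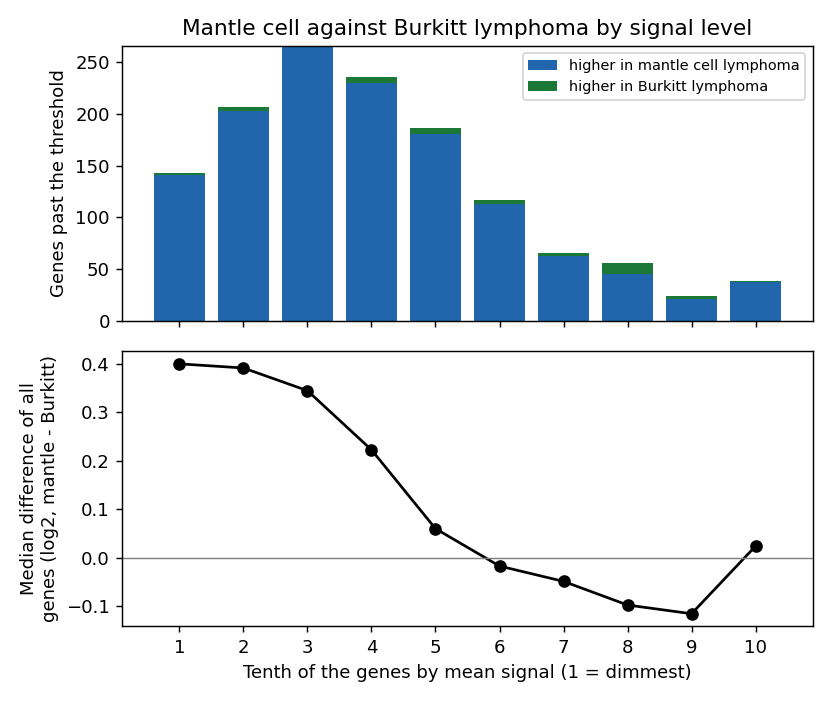
Comparison of MCL with BL by signal level: above, the number of genes past the threshold per decile of the 20181 genes by mean log2 signal, coloured by the type in which they were higher, and below, the median log2 difference of all genes in that decile. The median falls from 0.40 in decile 1, the dimmest, to -0.12 in decile 9.

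The 9 genes chosen in advance for every comparison did not pass the threshold in any of them in the standard setting. In some alternatives Ccnd1 (lowest adjusted p = 0.00642), Sdc1 (0.0105), Bcl6 (0.0164), Trp53 (0.0415) and Pax5 (0.0477) passed between PCL and MCL, and Sdc1 (0.00645) and Ccnd1 (0.00839) between PCL and BL. Myc, the oncogene carried by the transgene, had a log2 signal of 4.51 ± 0.55 (SD, n = 4) in PCL, 4.67 ± 0.23 (SD, n = 3) in MCL and 4.26 ± 0.45 (SD, n = 4) in BL, with adjusted p from 0.589 to 0.812. For Trp53, for which the mice were heterozygous, the differences were 1.23 between PCL and MCL (adjusted p = 0.279) and 0.58 between PCL and BL (adjusted p = 0.668), with PCL1 at -2.39 and the nearest PCL tumour at -0.19. Cyclin D1, encoded by Ccnd1, had a difference of -2.43 between PCL and MCL (adjusted p = 0.0509) and of 0.12 between MCL and BL (adjusted p = 0.949). Prdm1, a regulator of plasma cell differentiation, had a difference of 1.68 between PCL and BL (adjusted p = 0.141) and Sdc1 of 2.04 between PCL and MCL (adjusted p = 0.125). Irf4, Pax5, Bcl6 and Cdkn2a differed by -0.02, 0.52, 1.15 and -0.36 between PCL and MCL (adjusted p = 0.982, 0.279, 0.257 and 0.378).

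Of the 22 lists, 15 did not pass in any comparison. Their lowest adjusted p over the 3 comparisons was 0.084 for granulocyte markers, 0.114 for Myc targets, 0.151 for germinal centre genes, 0.181 for Burkitt lymphoma associated genes and 0.21 for immunoglobulin constant regions. Of the 17 genes in that last list only 3 were measured under a name it holds, and the probes of IgM and most IgG heavy chains carry other names, so its test does not cover the constant regions. It was 0.397 each for mantle cell lymphoma associated genes, the secretory pathway and the Bcl2 family, and 0.401 for immediate early and erythroid genes. It was 0.533 for the interferon response, 0.535 for stroma and endothelium, 0.64 for p53 targets and cytotoxic cell markers and 0.767 for T cell markers. Summed over the lists, 23 members were called between PCL and MCL, 3 between PCL and BL and 5 between MCL and BL, and adjusted over the list alone these counts were 33, 24 and 6. With the correlation between genes estimated from the data, 0 of 22 lists passed in any comparison, also at an unadjusted p under 0.05. The test fry called 0 lists for movement in one direction and 13, 9 and 0 for change in either direction.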

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

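Of the tests in this part, those of the offset between arrays, the spike-in transcripts, RNA integrity, the called genes of chromosome 6 and the loss of copies were chosen only after the results were seen.

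Nearly all genes that differed between MCL and BL were higher in MCL, 97.0% of 1341. An offset that changes with signal level was tested by quantile normalization, which gives all arrays the same distribution of signals. It left 754 calls of which 95.0% were higher in MCL, with 90.8% to 97.4% over all alternatives. An offset shared by all genes of a signal level thus does not explain the direction alone. Quantile normalization does not undo the background treatment of dim probes, and with normexp correction only 65 genes were called. A difference in labelling or hybridisation between the slides cannot be told apart from lymphoma type, because each type has its own slide, and the spike-in transcripts, which hold no tumour RNA, were also higher on the MCL slide by a median of 0.42 (0.26 to 0.44 over 7 levels, log2). A true difference between the types stays open as well and was not tested separately. The dimmest spike-in levels, below the floor, differed by -0.21, 0.03 and 0.18, without a shared direction. The spike-ins thus cannot show whether the direction of the small differences among dim genes came from the slides, which stays possible. The median size of the called differences was 1.04.

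PCL1 stood apart from PCL2 to PCL4 in its correlations, and 9 of the 13 genes with an outlying tumour named here had PCL1 as that tumour. Most of these genes were named for differences between types in the same data, so the count is no independent support. The 13 came from 170 checks of genes, where chance gives 8.5. RNA from macrophages in the other PCL tumours was tested by leaving out the macrophage markers and the 1000 genes that correlate best with them, and PCL1 still correlated at a mean of 0.953 with PCL2 to PCL4, below the lowest correlation among those, 0.975, and at a mean of 0.952 with the BL tumours, although 17 of 17 macrophage genes were lower in PCL1 by a median of -2.96. With all genes, PCL1 correlated at a mean of 0.945 with PCL2 to PCL4 and of 0.952 with the BL tumours. Without the genes left out, its means with PCL2 to PCL4 and with BL were nearly equal, at 0.953 and 0.952. The markers were highest in PCL2 to PCL4, so the 1000 genes can include tumour cell genes that set PCL1 apart. Leaving such genes out also brings PCL1 nearer to PCL2 to PCL4. The change therefore cannot show whether macrophage RNA had made PCL1 closer to BL. PCL3, with the same integrity number of 9, correlated at 0.977 with PCL2 and PCL4, so that number did not set PCL1 apart from PCL3. A single other array cannot exclude an effect of RNA quality. A Burkitt lymphoma under a plasma cell label stays open: on a scale from BL (0) to PCL2 to PCL4 (1), PCL1 lay at 0.247, left-out BL tumours at 0.0540 to 0.203 with an SD of 0.0659 and left-out PCL tumours at 0.887 to 0.975. Some genes followed the label, such as Slpi (5.28 in PCL1, at most 1.64 in BL) and Prss12 (1.23 and at most -3.59), although they were named because PCL and BL arrays did not overlap, and no biological explanation was tested, since the design names no difference within a type.

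Genes of chromosome 6 had a median difference of -0.54 between PCL and the mean of the other types. It was taken over 454 genes with signals above the median of all genes, 84.4% of them lower. The difference did not pass 0.05 after adjustment (exact permutation test over 330 assignments, two-sided, p = 0.00606, adjusted p = 0.0606 over 20 chromosomes). Chromosome 7 had the same p and adjusted p, with a median of -0.37 and 80.5% of 754 genes lower, and no explanation was tested for it. The shift of chromosome 6 was spread over most of its genes, as the 84.4% that were lower show. Its median without the 40 called genes was -0.52, against -0.35 as the lowest of the other chromosomes, that of chromosome 7. A median over 454 genes moves little when 40 are left out, so this check adds little. The signal level of the chromosome 6 genes does not account for the shift, since the lowest median of 10000 gene sets of matched signal from other chromosomes was -0.048. A loss of copies in PCL2 to PCL4 is a candidate explanation: all 8 stretches of 20 Mb along the chromosome were lower in these tumours, with medians from -0.67 to -0.15, while the chromosome's median in PCL1, on the same slide, was 0.04, and BL1 was the highest tumour, at 0.56. It remains a hypothesis, found and tested on the same data, and DNA was not analysed here.

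Other splits of the samples into groups of the same sizes were fitted in the same way. For the F test, 1 of 100 splits drawn, the real one, gave 1701 genes, and the highest other split gave 950, so the share was under 0.05. Between PCL and BL, 1 of 35 splits gave 133 genes and the highest other 61. Between MCL and BL, 1 of 35 gave 1341 and the highest other 19. The real split alone is the smallest share that 35 splits can give, and the shares were not adjusted over the comparisons. The splits also cannot tell lymphoma type from slide. Between PCL and MCL, 2 of 35 splits gave 1401 or more, and chance cannot be excluded at a share of 0.05. The other split set PCL1 with the 3 MCL tumours against PCL2 to PCL4 and gave 1476 genes, so the samples hold a structure in which PCL1 is apart from its group. For the number of lists chance cannot be excluded: 34 of 35 splits gave at least the 1 list found between PCL and MCL (highest other 9), 9 of 35 at least the 6 between PCL and BL (highest other 9) and 31 of 35 at least the 1 between MCL and BL (highest other 12).

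Among groups of 4 tumours, a tumour lay far from the others of its type in 16 of 224 checks, where chance gives about 1 in 20, or 11.2. The following are log2 signals, with the nearest tumour of the type in brackets. In PCL1 they were 3.38 for Rd3l (5.83), -5.41 for Trim63 (1.83), -2.02 for Arap3 (1.26), 6.02 for Eif4a1 (6.34), -2.39 for Trp53 (-0.19) and -3.82 for Tdrd9 (1.46). Also in PCL1, Slc40a1 was at -4.84 (-0.81), Snrpn at -4.42 (-7.29) and Il7r at -2.23 (1.38). In BL4, Hey1 was at -5.38 (-7.63) and Blk at 0.36 (0.65). Pls1 was at -5.57 in BL1 (-8.13), and Kdr at 2.53 in PCL3 (2.01). The median of the Burkitt lymphoma associated list was -0.19 in PCL4 (-0.10), and that of the stroma and endothelium markers was 1.51 in BL3 (-0.37). The median local background was 24 intensity units in PCL4 and 26 in the nearest other PCL array.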

How the results depend on the processing

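Of 29 alternatives, the 3 restricted to named genes, to genes with a mean signal above the median and to genes outside chromosomes 6 and 7 were chosen after seeing the data. Leaving out single arrays gave 333 to 2463 genes between PCL and MCL, 5 to 1074 between PCL and BL, 687 to 1373 between MCL and BL and 717 to 2827 in the F test. The F test gave 2827 without PCL1, 717 without PCL2, 845 without PCL3, 780 without PCL4, 850 without MCL1, 735 without MCL2, 915 without MCL3 and 1017 without BL2. Between PCL and MCL the count was 2463 without PCL1, 333 without PCL2, 551 without PCL3, 338 without PCL4, 693 without MCL1, 476 without MCL2 and 700 without MCL3. Between PCL and BL it was 1074 without PCL1, 5 without PCL2, 37 without PCL3, 28 without PCL4, 36 without BL2, 45 without BL3 and 64 without BL4, and between MCL and BL 687 without MCL1, 740 without MCL2 and 754 without BL2. The share of distance between types was 33.3% to 42.6% in these fits.

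With normexp background correction the counts were 197 between PCL and MCL, 13 between PCL and BL, 65 between MCL and BL and 131 in the F test, of which 194, 13, 65 and 130 were also called in the standard setting. The share of distance was 28.2% (exact permutation p = 0.075), the only alternative in which the grouping lost its call. Normexp moved the median difference of all genes from -0.03 to 0.16 between PCL and MCL and from 0.06 to -0.10 between MCL and BL, and its calls between PCL and MCL were 91 higher and 106 lower in PCL, against 429 and 972. Between PCL and BL the calls were 92 higher and 41 lower in the standard setting, 55 and 39 with quantile normalization, 5 and 8 with normexp and 84 and 82 in the authors' value table. Between MCL and BL, quantile normalization gave 754 genes, the values of the authors 680 and a minimum of 2-fold 732. With no filter on dim probes the counts were 697, 86 and, in the F test, 1050. Array weights gave 4424, 2183 and 4763, with weights from 0.38 for PCL1 to 2.79 for PCL2. A fit of only the groups compared gave 742 between PCL and MCL and 291 between MCL and BL. Only named genes gave 688, 510 between MCL and BL and 893 in the F test, and genes above the median signal 475, 60, 226 and 421. Without chromosomes 6 and 7 there were 78 between PCL and BL, 70 higher and 8 lower in PCL, while genes above the median signal gave 18 higher and 42 lower there. The causes of these changes were not tested. A block by slide was not run, since it could not be fitted.

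The array position as a replicate block gave 391 genes between PCL and MCL, 64 between PCL and BL, 380 between MCL and BL and 341 in the F test, and of 76 calls of genes named in the text 33 held. Arrays of a position share only a number: their deviations from the type means correlated at -0.046 to 0.172 over 10 pairs, with 3 above 0.1, although 8 of 11 arrays correlated best with their own position, a hint from the data and not from the design.

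None of the list calls held with an estimated correlation or with fry, which gave 0, 0 and 0 lists. For macrophage markers the adjusted p was 0.829 and 0.20 between PCL and MCL. Between PCL and BL it was 0.638 and 0.241 for the plasma cell programme, mature B cell, cell cycle, NF-kB and macrophage lists and 0.647 and 0.490 for MHC class II, and for precursor B cells between MCL and BL 0.916 and 0.964. The number of lists between PCL and MCL, 1 in the standard setting, was 8 with normexp, 3 without a filter, 3 with weights and 2 with the mean of probes. Between MCL and BL, also 1 there, it was 4 with normexp, 2 without a filter, 2 with weights, 2 with the integrity number and 0 with only probes well above background on all arrays. In single settings the adjusted p was as follows, and the cause was not tested. With normexp it was 0.0319 for precursor B, 0.000128 for MHC class II, 0.0468 for immunoglobulin regions and the interferon response, 0.0387 for cell cycle, 0.00142 for NF-kB and 0.0112 for granulocytes between PCL and MCL. With normexp it was also 0.0421 for granulocytes between PCL and BL, and 0.0424 for the plasma cell programme and interferon response and 0.0371 for MHC class II between MCL and BL. With weights it was 0.0154 for precursor B and granulocytes between PCL and MCL and 0.041 for macrophages between MCL and BL. Without a filter it was 0.00544 for MHC class II and 0.00805 for NF-kB between PCL and MCL, 0.115 for the plasma cell programme between PCL and BL and 0.0251 for cell cycle between MCL and BL. With the mean of probes it was 0.0417 for MHC class II between PCL and MCL. For MHC class II between PCL and BL it was 0.131 with quantile normalization, 0.133 in the authors' value table, 0.0557 with only probes well above background on all arrays and 0.0587 with the integrity number, and it ranged from 0.00206 to 0.647 over all alternatives. For Myc targets there it was 0.0473 in the authors' value table, for precursor B between MCL and BL 0.364 with only probes well above background, and for cell cycle there 0.0374 with the integrity number.

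Leaving out single arrays gave 1 to 6 lists between PCL and MCL (4 without PCL1, 2 without MCL1, 6 without MCL2, 3 without MCL3), 4 to 6 between PCL and BL and 0 to 5 between MCL and BL (2 without PCL1, 2 without MCL1, 5 without MCL2, 0 without MCL3, BL2, BL3 or BL4, 4 without BL1). Without MCL1, where the interferon list was at 4.40, the interferon response reversed, to adjusted p = 0.00945 between PCL and MCL and 7.47e-05 between MCL and BL.

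Without single arrays the adjusted p of lists also passed or lost the threshold, and the cause was not tested. Between PCL and MCL it ranged from 0.00512 to 0.365 for precursor B (0.0235 without PCL1, 0.00512 without MCL2) and from 0.0045 to 0.433 for MHC class II (0.00697 without PCL1, 0.0191 without MCL2, 0.0045 without MCL3). It ranged from 0.0191 to 0.52 for NF-kB (0.0191 without MCL2, 0.039 without MCL3) and from 0.00945 to 0.699 for the interferon response (0.0191 without MCL2). For granulocytes it ranged from 0.00697 to 0.318 (0.00697 without PCL1, 0.0437 without MCL2).

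Between PCL and BL the adjusted p ranged from 0.0152 to 0.119 for the plasma cell programme (0.0533 without PCL2, 0.0725 without PCL3, 0.0859 without PCL4, 0.119 without BL1, 0.0613 without BL2). For mature B cells it ranged from 0.00229 to 0.065 (0.0554 without PCL1, 0.065 without BL3). For MHC class II it ranged from 0.00349 to 0.125 (0.0594 without PCL2, 0.125 without PCL3, 0.0859 without PCL4, 0.0517 without MCL2, 0.0725 without BL1, 0.117 without BL3, 0.0718 without BL4). For Myc targets it ranged from 0.0132 to 0.758 (0.0132 without BL2).

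Between MCL and BL the adjusted p ranged from 0.000897 to 0.24 for precursor B (0.24 without MCL1, 0.0659 without MCL3, 0.0629 without BL2, 0.0716 without BL3, 0.102 without BL4). Without MCL2 it was 0.0476 for mature B cells (up to 0.595 without another array), 0.000925 for cell cycle (up to 0.722), and 0.0202 for immediate early genes and for erythroid markers (each up to 0.828). Without BL1 it was 0.0497 for Burkitt lymphoma associated genes (up to 0.389), 0.046 for granulocytes (up to 0.497) and 0.0313 for immediate early genes. For macrophages it ranged from 0.000817 to 0.716 (0.0255 without PCL1, 0.000817 without MCL1), and for the interferon response from 7.47e-05 to 0.939.

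Of 119 differences of genes named in the text, 76 were called, and 0 changed direction in an alternative that called them. Of the 76 calls, 68 held with quantile normalization, 20 with normexp, 65 with the values of the authors, 51 without a filter, 41 with only the groups compared, 70 with array weights, and 31 to 72 without single arrays (31 without PCL2 and 31 without PCL4). Calls were also gained, 21 with array weights and 16 without PCL1.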

Other observations

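The observations in this part were all chosen after the values were seen, and none was tested beyond the adjusted p given.

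Several probes of IgG heavy chains were bright in all PCL tumours. The log2 signal of an IgG2b probe was 3.92, 4.37, 5.32 and 5.91 in the 4 PCL tumours and -0.72, -1.46 and -0.88 in the MCL tumours (limma, adjusted p = 0.0432). It was -3.92, 4.33, 0.14 and -0.65 in the BL tumours (adjusted p = 0.113 against PCL), so BL2 was at the PCL level. The IgG2c probe differed between PCL and MCL with adjusted p = 0.0311 and the IgG2a probe with adjusted p = 0.0432. Constant regions are similar in sequence, so these probes can share signal. Another IgG2b probe was dimmer, at -4.09, -1.43, -0.68 and 0.36 in the PCL tumours (adjusted p = 0.0582 against MCL). Of the IgG1 probes, 1 followed this order (adjusted p = 0.0223) and another did not (adjusted p = 0.473). The IgM heavy chain lay between 4.92 and 6.51 in all 11 tumours and a kappa constant region probe between 5.32 and 6.92. The probe named Igkc was not as even. It differed by -1.84 between PCL and MCL and by -1.17 between PCL and BL, neither of them called.

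The lambda-1 variable probe differed within types. It was at -1.14 in PCL1 and 4.50, 7.18 and 6.87 in PCL2 to PCL4, and at 6.73, 5.13, 0.85 and 1.69 in the BL tumours. In the MCL tumours it was at -1.39, -1.48 and -1.88.

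Sex-linked genes differed between tumours of a type. Xist was highest in PCL2 (0.91), PCL3 (0.19), MCL1 (-1.47), MCL3 (1.43), BL3 (0.63) and BL4 (-0.10). The Y-linked gene Ddx3y was highest in PCL1 (-0.41), PCL4 (-0.03), BL1 (-1.14) and BL2 (0.77). MCL2 was low for both, with -7.95 for Xist and -6.19 for Ddx3y, but its signal of the Y-linked gene Eif2s3y, -5.0, was well above background. The sex of the mice is not given in the sources used here.

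The medians of some chromosomes stood out in single tumours. In medians of centred log2 signals, chromosome 7 was at -0.49 in PCL2, -0.32 in PCL4, -0.13 in PCL3 and 0.04 in PCL1. In BL1, chromosome 5 was at 0.42, chromosome 6 at 0.56 and chromosome 10 at -0.59. In BL2, chromosome 12 was at 0.37 and chromosome 13 at -0.44, and in MCL3 chromosome 12 was at -0.46.

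Some lists stood out in single tumours. The median of the interferon response list was 4.40 in MCL1 and between -1.32 and 0.89 in the others. The granulocyte markers had a median of 3.13 in PCL2. MHC class II genes had a median of 1.19 in MCL1 and of 0.39 in PCL1, against -0.59, -0.76 and -0.86 in PCL2 to PCL4.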
